A study of Mus musculus with 4 samples.

How the data were processed

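Bulk RNA sequencing was measured in 4 libraries of mouse primary T cells, 1 per biological replicate. The deposited values are raw fragment counts per gene, 1 table per library, not pooled and not normalized. Per the file headers, the authors counted read pairs with featureCounts 1.4.6-p4 on exons summed by gene of GENCODE mouse release 13, requiring both ends to align and counting on the reverse strand. Per the file headers, the command set no option for multimapping reads or for reads that overlap several genes, so reads shared between near-identical copies can be missing from both. The alignment's name in the headers includes STAR, and the labels give the build as mm10. The aligner's version was not given in the sources used here. All 4 headers carried the same identifying string in the counting command, so the headers showed no split. That string does not show whether the cells or libraries were prepared in 1 batch.

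The design assumed expected counts and TPM in the deposited files. The files hold whole-number counts, so the count model was run on the counts as deposited, and TPM was computed here from the counts and the exon lengths in the files. Coordinates are those of the files, 1-based. Symbols and gene types came from GENCODE mouse release 21, matched on the Ensembl identifier without its version: 50376 of 50600 genes matched, and 27025 genes had 0 counts in all libraries. The unmatched genes held at most 0.01% of a library's counts. All 381 list members were measured, 3 of them matched by a synonym. Some list members stand in more than 1 list, Gzma and Sesn2 among them.

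Library totals ran from 49613182 to 94222415 counts, a ratio of 1.9. A gene with 0 counts was given a floor of 3 counts per library, converted to TPM with that library's own scale.

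Since the labels give 1 group, no test between groups was made and no replicates were paired. Detection was a TPM of at least 1 in every library. List detection was compared with all other protein-coding genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over 28 lists. Gene pairs were compared within libraries on log2(TPM + 1) by an exact two-sided sign-flip test over 16 sign patterns, adjusted over 17 pairs. The pseudocount of 1 understates differences of low genes. Variable genes were tested in edgeR 4.0.16 under R 4.3.3, with TMM factors, filterByExpr for 1 group, a trended dispersion and an intercept-only fit, by comparing each gene's deviance with a chi-square distribution on 3 degrees of freedom. List variability was the SD over libraries of the mean log2(TPM + 1) of members with a mean TPM of at least 1, in lists with at least 5 such members, against 10000 random lists of the same size matched in 20 expression bins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

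The tests were tested on simulated data. For variable genes, counts were drawn for 13681 genes from the real means, library sizes and trended dispersions, with genes changed in 2 of the 4 libraries. The trended dispersion is the one the test assumes, so the false calls do not show its error rate on the real data. The test recovered 28% of genes changed 1.5-fold, 74% at 2-fold, 90% at 3-fold and 98% at 4-fold, with 5 false calls among 150. For list variability over 11054 genes, 3 of 50 unchanged lists of 15 genes passed an unadjusted threshold of 0.05. So did 21 of 50 shifted by 0.1 on the log2 scale and 50 of 50 shifted by 0.2. Each gene was drawn independently, so genes that shift together, as with length, were not simulated.

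The tests, gene lists, pairs and the rule for named genes were fixed before the data were examined. The genes named are both genes of each pair; for each list its first gene, its 3 detected members of highest mean TPM and every transcription factor and cytokine of the 5 helper lists; the 10 protein-coding nuclear genes of highest mean TPM; the 10 variable genes of smallest p; the 3 members of largest SD in each list past the variability test; and all sex-chromosome genes. Some of these genes are not reported here. Other genes are named where a count needed it and were chosen after their values were seen.

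The alternatives tried were TPM thresholds of 0.5 and 5, a count of at least 10, mean TPM filters of 1 for detection and 5 for list variability, V genes with a mean count of at least 10, V usage by counts, composition by TPM, a pseudocount of 0.1, Spearman correlation, log2 CPM with TMM factors, DESeq2 1.42.0 size factors and dispersion outliers, a common dispersion, no filter or a mean count of at least 50, and leaving out each replicate in turn. Length and GC offsets or trends, removal of X- and Y-linked genes, length-matched random lists, V genes without pseudogenes and TPM over protein-coding genes were added after seeing the data.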

Results

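RNA was sequenced from primary T cells of C57BL/6NJ mice in 4 libraries, which the labels number as 4 biological replicates of 1 cell type. No treatment or second group was named, so the question addressed was which genes these cells expressed and how far the replicates differed. The file headers named all 4 samples as bulk activated cells at 72 h, with a sample name beginning mmTh0. The total count per library was 58522696, 53569919, 49613182 and 94222415 fragments for replicates 1 to 4. Of 21764 protein-coding genes, 10754 (49.4%) reached a TPM of 1 in every library, where TPM is the count scaled by gene length and by the library total. Values below are means ± SD over the 4 libraries in TPM unless stated. The labels gave all 4 libraries the same donor identifier, while Xist and the Y-linked genes of the fixed list divided them into replicates 1 and 2 and replicates 3 and 4. The edgeR p-values measure the spread between these libraries beyond that of genes of the same abundance, and the labels do not settle its source. Fisher p-values compare shares of genes, and sign-flip p-values rest on differences within libraries. List-variability p-values compare the spread between libraries with that of random gene lists. Intervals and floors from counts cover counting error only.

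Transcripts of CD4 T cells were abundant. All 20 genes of the T-cell identity list were detected, led by the receptor constant gene Trac (1768 ± 84.7), the surface receptor Cd5 (1567 ± 80.2) and the receptor constant gene Trbc2 (1442 ± 83.3). Cd4, the co-receptor for MHC class II (ENSMUSG00000023274, mm10, chromosome 6, 124864692 to 124888221, minus strand), stood at 1056 ± 62.8, and Cd3e, a signalling chain of the receptor, at 272 ± 15.5. The co-receptor gene Cd8a stood at 0.190 ± 0.0957 and its partner Cd8b1 at 15.8 ± 2.38. The difference in log2(TPM + 1) between Cd4 and Cd8a was 9.80 ± 0.13 (SD, n = 4), and that between Trac and the gamma-delta constant gene Trdc (0.729 ± 0.118) ran from 9.93 to 10.07 over the libraries. Both differences were positive in 4 of 4 libraries. Across all 17 fixed gene pairs the smallest p that 4 libraries allow in a two-sided exact sign-flip test is 0.125, which 15 pairs reached (adjusted p = 0.142), so no pair could pass the threshold. Detection of the T-cell identity list exceeded that of other protein-coding genes (two-sided Fisher exact test, adjusted p = 6.98e-06), a description across genes and not across replicates.

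Markers of most other cell types lay near the floor. None of the 9 gamma-delta T-cell, 9 natural killer and innate lymphoid, 10 neutrophil or 8 erythroid genes was detected in all libraries, fewer than among other protein-coding genes (Fisher exact test, adjusted p = 0.00844, 0.00844, 0.00499 and 0.0157). The gamma-delta call ended at a TPM threshold of 0.5 (Fisher exact test, adjusted p = 0.147 for list detection: gamma-delta T cell). None of the 6 platelet genes was detected either, without passing the threshold (Fisher exact test, adjusted p = 0.0515). The neutrophil gene S100a8, the globin gene Hbb-bs and the platelet gene Pf4 had 0 counts in all 4 libraries, which allows up to 0.310, 0.280 and 0.299 TPM in a library at 3 counts. The natural killer receptor Ncr1 stood at 0.0619 ± 0.0953, the B-cell receptor gene Cd79a at 0.896 ± 0.303, and the macrophage lysozyme gene Lyz2 had 1 count in replicate 3 alone. Cd3e exceeded Cd79a by 7.18 ± 0.26 and Lyz2 by 8.07 ± 0.06 on the log2(TPM + 1) scale (SD, n = 4). Single members of these lists were abundant. The immunoglobulin heavy-chain gene Ighm stood at 385 ± 32.2 beside the light-chain gene Igkc at 2.70 ± 1.09, and the invariant chain gene Cd74 at 397 ± 31.8 beside H2-Eb1 at 32.9 ± 6.24 and H2-Ab1 at 21.7 ± 4.44. The dendritic cell gene Itgax stood at 0.00644 ± 0.0129. Ms4a6c (22.7 ± 1.17), Cd68 (10.5 ± 0.88), Adgre1 (3.21 ± 0.525), Pecam1 (23.2 ± 0.862) and Pdgfrb (3.30 ± 0.191) were detected, as was Cd79b (2.55 ± 0.850), while the collagen gene Col1a1 stood at 0.807 ± 0.179. In all, 4 of 14 B-cell, 4 of 16 macrophage and monocyte, 4 of 12 dendritic cell and MHC class II, 2 of 11 fibroblast and endothelial and 3 of 8 immature thymocyte genes were detected. None of these 5 lists passed the test (Fisher exact test, adjusted p = 0.240, 0.108, 0.435, 0.0966 and 0.783). At a TPM threshold of 5 the B-cell and macrophage lists fell below other genes (Fisher exact test, adjusted p = 0.0184 for list detection: B cell and 0.0371 for list detection: macrophage and monocyte). In the thymocyte list, Themis stood at 22.0 ± 1.81 and Cd1d1 at 6.40 ± 0.331, and the recombinase gene Rag1 had 2 counts in replicate 4 alone.

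**Figure D1:**
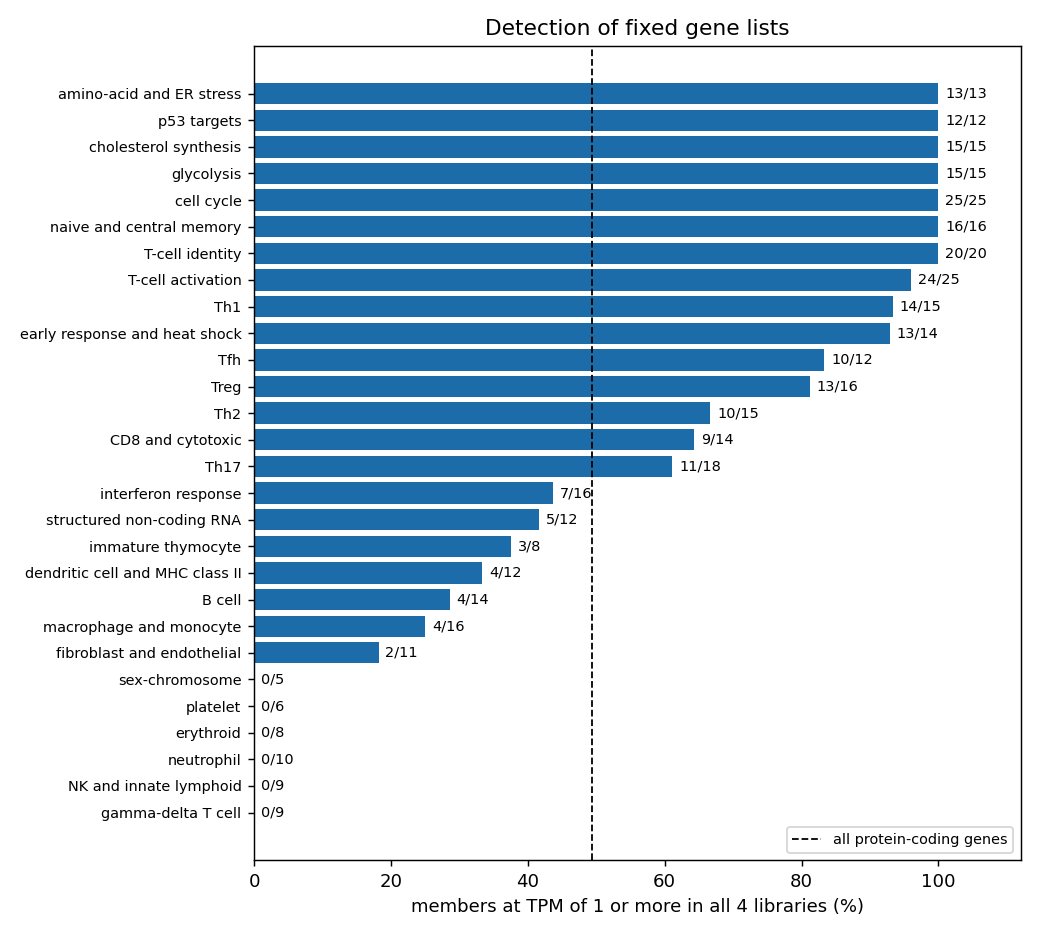
Share of each fixed gene list at 1 TPM or more in all 4 libraries, in percent, with detected over measured members beside each bar. The dashed line marks all protein-coding genes at 49.4%. T-cell, activation, cell-cycle and metabolic lists reach 96 to 100%, and no gamma-delta, natural killer, neutrophil, erythroid or platelet gene is detected.

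Activation genes were abundant. Of 25 activation genes 24 were detected (Fisher exact test, adjusted p = 6.98e-06). The costimulatory receptor gene Tnfrsf4 (mm10, chromosome 4, 156013843 to 156016612, plus strand) stood at 2363 ± 170, the growth factor gene Il2 (mm10, chromosome 3, 37120523 to 37125959, minus strand) at 1015 ± 71.5 and Nr4a1, a nuclear receptor induced by receptor signalling, at 889 ± 84.0. The early activation marker Cd69 stood lower, at 47.7 ± 3.79, and the adhesion receptor Cd44 at 262 ± 12.5. All 16 genes of the naive and central memory list were also detected (Fisher exact test, adjusted p = 8.79e-05). The homing receptor gene Ccr7 stood at 870.3 ± 140.9, the transcription factor gene Tcf7 at 332 ± 25.9 and Dapl1 at 325 ± 64.2.

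The cells expressed genes of division and of anabolic metabolism. All 25 cell-cycle genes were detected (Fisher exact test, adjusted p = 6.12e-07), with the proliferation marker Mki67 at 244 ± 45.3, the replication genes Mcm3 and Pcna at 515 ± 23.7 and 492 ± 27.7, and the ribonucleotide reductase gene Rrm2 at 502 ± 11.3. All 15 glycolysis and all 15 cholesterol synthesis genes were detected (Fisher exact test, adjusted p = 0.000119 for each). Lactate dehydrogenase A, encoded by Ldha, stood at 3342 ± 267 and Ldhb at 108 ± 8.05, a log2 difference of 4.94 ± 0.03 (SD, n = 4). Gapdh stood at 1597 ± 46.8, Pkm at 1585 ± 72.5 and the hexokinase gene Hk2 at 120.0 ± 10.8. The glucose transporter gene Slc2a1 (169 ± 12.8) exceeded Slc2a3 (20.7 ± 1.68) by 2.97 ± 0.16 on the log2 scale. In the cholesterol synthesis list, Hmgcs1 stood at 348 ± 26.4 and Cyp51 at 276 ± 17.1. The 10 most abundant protein-coding nuclear genes were Rplp1 (8905 ± 1309), Actb (7097 ± 305), Eef1a1 (6130.1 ± 218.6), Rpl8 (6003 ± 565), Rplp0 (5790.1 ± 499.6), Eef2 (5618 ± 322), Hsp90ab1 (4946 ± 223), Rpl4 (4196 ± 149), Rps2 (4149 ± 306) and Ldha.

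Genes from the lists of several helper T-cell lineages were expressed in the same libraries. Bulk levels of list members do not show that cells of those lineages were present. The Th2 transcription factor gene Gata3 stood at 51.0 ± 3.57. The Th1 factor gene Tbx21 stood at 3.92 ± 0.869 and the regulatory T-cell factor gene Foxp3 at 2.74 ± 0.948. Within libraries, the difference of Tbx21 minus Gata3 was -3.42 ± 0.27 and that of Foxp3 minus Tbx21 was -0.41 ± 0.22 on the log2(TPM + 1) scale (SD, n = 4; 4 of 4 libraries each). Among the cytokines, Il17a stood at 6.80 ± 1.26, Il17f at 30.0 ± 2.84, Ifng at 1.23 ± 1.16 and Il4 at 1.04 ± 0.376. Il17a exceeded Ifng by 1.91 ± 0.66 and Il4 by 1.94 ± 0.42. The difference between Ifng and Il4 was 0.03 ± 0.48 and changed sign between libraries (exact sign-flip p = 1), and Ifng in replicate 1, at 2.95, drove its mean, which was 0.664 without that library.

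Of 15 Th1 genes 14 were detected (Fisher exact test, adjusted p = 0.00141), with the chemokine genes Ccl4 and Ccl3 at 795 ± 81.8 and 545 ± 65.4, and Lta, Tnf and Ccl5 at 366 ± 41.7, 248 ± 37.2 and 32.0 ± 7.22. Stat4 stood at 109 ± 7.62 and Hlx at 2.49 ± 0.252. Of 15 Th2 and 18 Th17 genes, 10 and 11 were detected, not more than among other genes (Fisher exact test, adjusted p = 0.261 and 0.413). The Th2 list held Stat6 at 335 ± 19.1, the chemokine receptor genes Ccr4 and Ccr8 at 194 ± 8.25 and 155 ± 14.0, Gfi1 at 101 ± 2.09, Il13 at 30.0 ± 6.16, Areg at 8.04 ± 2.12, Pparg at 4.30 ± 0.708, Il5 at 0.491 ± 0.336 and Il10 at 0.0648 ± 0.0802. In the Th17 list the chemokine receptor gene Ccr6 stood at 632 ± 46.8, Csf2 at 189 ± 18.1, Stat3 at 162 ± 13.6, Nfkbiz at 46.9 ± 4.38, Ahr at 20.9 ± 2.51 and Rora at 17.2 ± 2.77. Maf (0.823 ± 0.120), Ccl20 (0.608 ± 0.243), Il22 (0.0625 ± 0.0916) and Il21 (0.0328 ± 0.0360) lay below 1 TPM. Of 16 regulatory T-cell genes 13 were detected (Fisher exact test, adjusted p = 0.0220), led by Tnfrsf18 (1032 ± 65.1), the inhibitory receptor gene Ctla4 (776 ± 41.5) and Capg (510.2 ± 30.1), with Ebi3 at 332 ± 16.3, Tgfb1 at 191 ± 11.9, Ikzf2 at 12.1 ± 2.52 and Ikzf4 at 11.3 ± 1.77. Of 12 follicular helper genes 10 were detected (Fisher exact test, adjusted p = 0.0368), with the inhibitory receptor gene Pdcd1 at 683 ± 37.9, Cd40lg at 488 ± 27.5, Btla at 427 ± 32.4, Pou2af1 at 49.9 ± 5.38, Tox at 37.5 ± 3.66 and Bcl6 at 11.4 ± 1.83. Tox2 stood at 0.164 ± 0.141 and Ascl2 had 0 counts in all 4 libraries, which allows up to 0.133 TPM. Of 14 CD8 and cytotoxic genes 9 were detected (Fisher exact test, adjusted p = 0.361), with the apoptosis ligand gene Fasl at 93.9 ± 4.74, Runx3 at 65.4 ± 5.14 and Nkg7 at 28.9 ± 3.14. At a TPM threshold of 5 the Th1, Treg and Tfh lists no longer passed (Fisher exact test, adjusted p = 0.515 for list detection: Th1, 0.184 for list detection: Treg and 0.0609 for list detection: Tfh), and at 0.5 list detection: Tfh did not either (adjusted p = 0.0700, Fisher exact test).

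**Figure D2:**
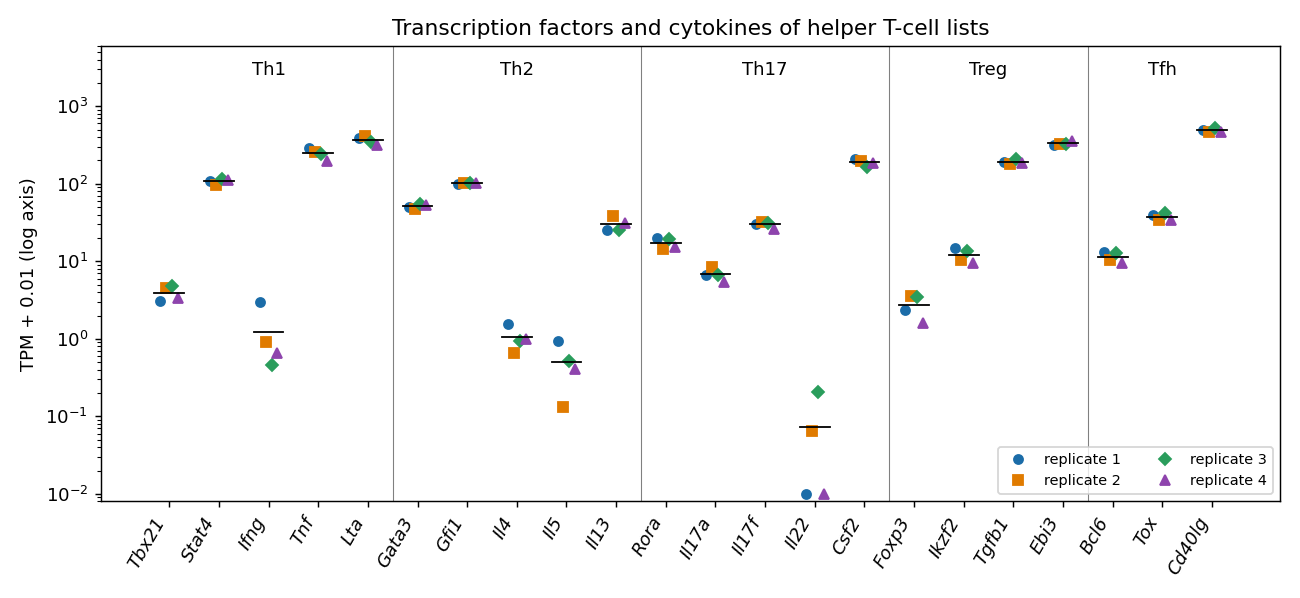
Transcription factor and cytokine genes of 5 helper T-cell lists in each library, in TPM with 0.01 added, on a log axis. Symbols are the 4 replicates and bars their mean. Gata3 lies above Tbx21, and Tbx21 above Foxp3, in every library, and Ifng, Il4 and Il5 lie near 1 TPM or below except for Ifng in replicate 1 at 2.95.

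Stress-related lists were detected in full or nearly so, and the interferon list was not. All 12 p53 target genes were detected (Fisher exact test, adjusted p = 0.000739), with the cell-cycle inhibitor gene Cdkn1a at 985 ± 48.8, Ccng1 at 792 ± 32.1 and the pro-apoptotic gene Bax at 493 ± 53.1. All 13 amino-acid and ER stress genes were detected (Fisher exact test, adjusted p = 0.000417), with the chaperone gene Hspa5 at 691 ± 12.2, Atf4 at 637 ± 19.0, Phgdh at 319.5 ± 28.2 and Ddit3 at 19.7 ± 1.36. Of 14 early response and heat shock genes 13 were detected (Fisher exact test, adjusted p = 0.00241), led by Hspa8 (1751 ± 56.0), Junb (1425 ± 68.9) and Jund (1296 ± 90.8), with Fos at 18.2 ± 1.44. Of 16 interferon response genes 7 were detected (Fisher exact test, adjusted p = 0.804). Bst2 stood at 311 ± 34.3, Gbp2 at 60.1 ± 3.54 and Isg15 at 8.50 ± 4.39.

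Many T-cell receptor V genes were in use. From TPM, the effective number of Trbv genes (the exponential of the Shannon entropy) was 15.9 ± 0.22 (SD, n = 4) among 35 listed, and that of Trav genes was 47.5 ± 2.14 among 128. The most used Trbv gene was Trbv13-2 at 14.2 ± 0.578% of Trbv TPM, followed by Trbv31 at 11.4 ± 0.358% and Trbv16 at 9.37 ± 0.584%. The most used Trav gene, Trav14n-3, took 6.33% of Trav TPM. These values rest on 11142 to 23483 Trbv counts and 4229 to 8281 Trav counts per library. Some V genes are near-identical copies whose reads can be split or left uncounted, so the share of a single gene is uncertain.

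Replication-dependent histone mRNAs, which lack a poly(A) tail, made up little of the libraries. The 65 genes of the replication-dependent histone clusters took 0.00313 ± 0.000427% of counts (SD, n = 4). Ribosomal protein genes took 4.26 ± 0.539%, mitochondrial genes 0.669 ± 0.148%, immunoglobulin genes 0.0222 ± 0.0023%, and T-cell receptor genes 0.142 ± 0.00807%. The 10 genes with the most counts of any type, ranked without regard to length and so another set than the 10 of highest TPM, took 3.53 ± 0.110%. Of 12 genes in the structured non-coding RNA list 5 were detected (Fisher exact test, adjusted p = 0.803), with Malat1 at 57.0 ± 28.8, Rn7sk at 18.3 ± 5.13 and Neat1 at 11.3 ± 2.5. No spike-in sequence was listed. The labels name the assay as total RNA, and the library protocol they link is named for polyadenylated RNA.

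The replicates were close to one another. The lowest of the 6 pairwise Pearson correlations of log2(TPM + 1) over 11054 protein-coding genes was 0.992, between replicates 2 and 3, and the highest 0.996, between replicates 2 and 4. These are correlations across genes, which are not independent replicates. A chi-square per degree of freedom of 14.9 to 32.7 between the counts of each pair showed that no library was another deposited again.

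Which genes differed between the libraries by more than genes of the same abundance was tested with edgeR. Of 13681 genes, 94 did so at an adjusted p under 0.05 (959 at an unadjusted p under 0.05), and the biological coefficient of variation was 11.1%. Xist, the RNA that silences an X chromosome, led (ENSMUSG00000086503, mm10, chromosome X, 103460375 to 103483217, minus strand). It stood at 332, 150.1, 0.877 and 0.392 TPM in replicates 1 to 4. The Y-linked gene Ddx3y (mm10, chromosome Y, 1260771 to 1286629, minus strand) stood at 0.0344, 0.0834, 49.0 and 45.8 TPM, from 3, 7, 3546 and 6620 counts. Eif2s3y, Uty and Kdm5d had 5 to 11 counts in each of replicates 1 and 2 and 2035 to 5818 in each of replicates 3 and 4. The filter on low counts kept all 4 Y-linked genes of the list out of the test, and the difference between Xist and Ddx3y had 1 sign in 2 libraries and the other in 2 (exact sign-flip p = 0.75). Since none of the 5 sex-chromosome genes reached 1 TPM in all libraries, their list had 0 detected genes and did not pass the test (Fisher exact test, adjusted p = 0.0966), although at a TPM threshold of 0.5 it fell below other genes (Fisher exact test, adjusted p = 0.0486 for list detection: sex-chromosome). Gm47283 and Mid1-ps1, also placed on the Y chromosome and named here after their values were seen, took another order. They had 207 to 715 counts in each of replicates 1 and 2, where the listed Y-linked genes had 3 to 11. Their levels therefore do not show whether a Y chromosome was present. Gm47283, one of the 94, stood at 27.8, 11.4, 34.4 and 40.1 TPM in replicates 1 to 4, and the pseudogene Mid1-ps1 at 20.1, 35.5, 10.8 and 0.0288 TPM, the last from 1 count. The X-linked gene Kdm6a stood at 47.9, 41.0, 29.2 and 24.4 TPM (edgeR adjusted p = 9.81e-08), and Mid1 (mm10, chromosome X, 169685199 to 170005736, plus strand) at 12.6, 15.6, 5.61 and 1.60 TPM (edgeR adjusted p = 2.34e-45).

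**Figure D3:**
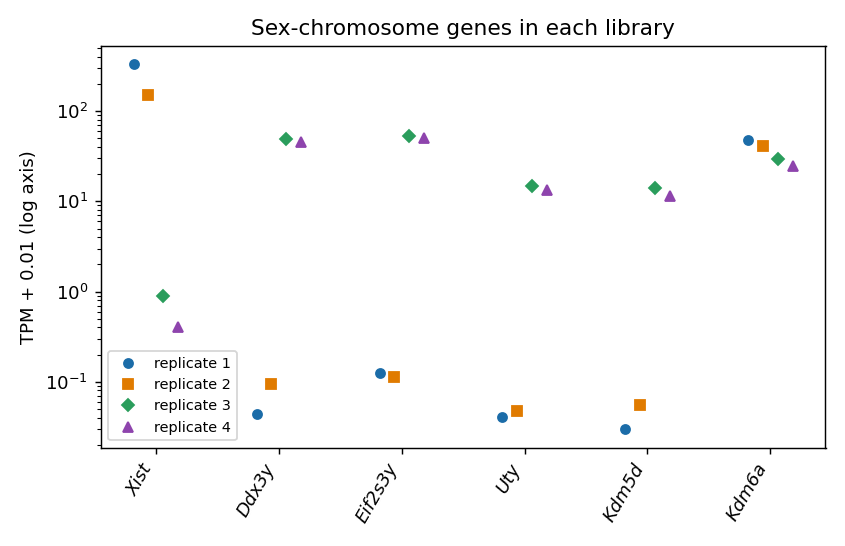
Sex-chromosome genes in each library, in TPM with 0.01 added, on a log axis, with 1 symbol per replicate. Xist lies at 332 and 150.1 TPM in replicates 1 and 2 and below 1 TPM in replicates 3 and 4, where the 4 Y-linked genes of the fixed list lie between 11.5 and 52.9 TPM.

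The other named variable genes lay on autosomes. Malat1 stood at 96.3, 30.5, 59.6 and 41.5 TPM in replicates 1 to 4 (edgeR adjusted p = 9.24e-23), and the unnamed transcript Gm42047 on chromosome 8 at 248, 103, 200.4 and 80.8 TPM (edgeR adjusted p = 1.02e-20). Gm43305 on chromosome 14 was 3.18 times as high in its highest library as in its lowest, the phosphatase gene Alpl 4.22 times, Cdk5rap1 2.87 times, Marveld2 5.22 times and Bin2 1.79 times. The variable gene Marveld2 was no longer called without replicate 1 (edgeR adjusted p = 0.454, against at most 1.99e-08 under the other settings). Of the genes in the fixed lists, Xist, Malat1 and Dapl1 were called over all genes, 1 in each of their lists. Adjusted over the list alone, the sex-chromosome and the naive and central memory lists kept 1 call each and the structured non-coding RNA list had 2 (Malat1 and Neat1). Adjusted over the list alone, the interferon list had 2 (Isg15 and Bst2) against 0 over all genes, and the Treg (Ikzf2), glycolysis (Slc16a3), p53 (Eda2r) and amino-acid and ER stress (Atf3) lists had 1 each against 0 over all genes. The other lists had 0 by either count. Of the 94 genes 10 lay on the X or Y chromosome, 4 were among the 77 ribosomal protein genes tested, 16 among the 1050 tested with summed exons of up to 1 kb and 20 among the 1899 with over 8 kb. The count of 94 fell to 46, 38 and 46 without replicates 1, 2 and 4 and rose to 617 with a common dispersion. With length and GC offsets, chosen after seeing the data, 111 genes were called, of which 61 were among the 94. Of the 94 genes 33 were higher in each of replicates 2 and 4 than in either of replicates 1 and 3. Other called genes took the reverse order, Malat1, Gm42047, Kmt2a and Mdn1 among them. Neither the genes in reverse order nor the share with either order among all tested genes was counted. Whether the 33 are an excess was therefore not tested.

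Some lists moved together between libraries. Of 16 lists tested, 5 had a larger SD of their mean log2(TPM + 1) than random lists matched on expression (one-sided permutation test with 10000 random lists). These were T-cell activation (SD 0.071, adjusted p = 0.0112), glycolysis (0.071, adjusted p = 0.0248), the interferon response (0.167, adjusted p = 0.0248), amino-acid and ER stress (0.096, adjusted p = 0.0248) and naive and central memory (0.095, adjusted p = 0.0282). The amino-acid and ER stress list deviated by -0.09, -0.07, 0.05 and 0.11 in replicates 1 to 4 and the naive and central memory list by -0.09, -0.07, 0.09 and 0.07, so both were lower in the libraries with Xist and higher in those with the Y-linked genes of the fixed list. The Th2, CD8 and cytotoxic, p53 target, and early response and heat shock lists, which did not pass, had the same signs. The Th1 list, which did not pass either, had the reverse signs (0.110, 0.003, -0.034 and -0.079 in replicates 1 to 4). The members of largest SD were Isg15, at 3.78, 9.34, 6.74 and 14.1 TPM in replicates 1 to 4, with Xaf1 and Ifit1; Atf3 (13.6 ± 3.87), Chac1 (4.45 ± 1.30) and Trib3 (7.22 ± 1.93); Egr1 (182 ± 30.2), Egr2 (80.0 ± 13.8) and Nr4a3 (145 ± 23.7); Slc16a3 (143 ± 20.6), Eno1 and Hk2; and Ccr7, Dapl1 and Satb1. The other lists did not pass, among them T-cell identity (SD 0.018) and cell cycle (0.032; permutation test, adjusted p = 0.740 and 0.176). All 5 calls ended when log2 CPM with TMM factors replaced TPM (permutation test, adjusted p = 0.0576 to 0.959, over a range of 0.0016 to 0.959 across all alternatives), and all 5 passed with a length and GC trend removed, an alternative chosen after seeing the data (permutation test, adjusted p = 0.0016 to 0.0266). Leaving out replicate 1 or replicate 4 left 1 list, T-cell activation, whose deviations of 0.03, -0.07, 0.09 and -0.04 in replicates 1 to 4 lay beside a shift of the TPM scale against TMM of 0.03, -0.06, 0.05 and -0.02.

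Transcripts also shifted with gene length. Among autosomal protein-coding genes, those with up to 1 kb of exons had a median log2 deviation from the mean of the libraries of -0.04, 0.18, -0.23 and 0.09 in replicates 1 to 4, and those over 8 kb 0.04, -0.10, 0.09 and -0.03. The 77 ribosomal protein genes, which are short, had a mean deviation of -0.02, 0.22, -0.28 and 0.08. Of these genes 4 were called variable, Rps29, Rps21, Rps27 and Rpl37, named here after their values were seen.

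**Figure D4:**
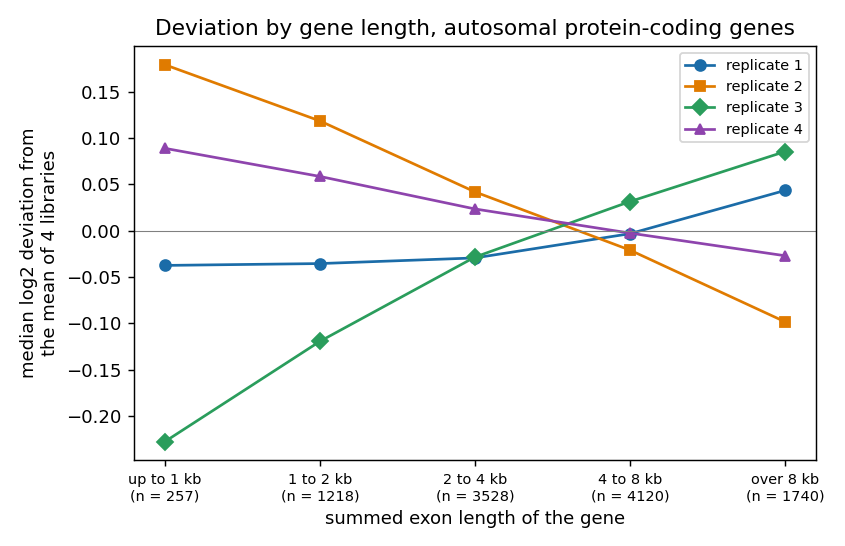
Median log2 deviation of autosomal protein-coding genes from the mean of the 4 libraries, by summed exon length in kb, with 1 line per replicate. Genes of up to 1 kb (n = 257) lie at 0.18 in replicate 2 and -0.23 in replicate 3, and genes over 8 kb (n = 1740) at -0.10 and 0.09.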

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

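No test in this part was chosen after the result was seen. Over the 4 libraries, 199 results were checked for a library that lay far from the other 3, by its gap to the nearest library over the whole range. Of these, 6 were singled out, fewer than the 9.95 that chance gives at about 1 in 20. Gfi1 was lower in replicate 1 (98.1 TPM) than in the others (102 to 103 TPM), with a gap of 0.922 of the range. Ctla4 was higher in replicate 4 (838 TPM against 749 to 763), with a gap of 0.842. Nkg7 was higher in replicate 2 (33.6 TPM against 26.8 to 27.8), with a gap of 0.840. Lyz2, Rag1 and Itgax each had a gap of 1.000, from 1 count in replicate 3, 2 counts in replicate 4 and 2 counts in replicate 2, with 0 counts in the other libraries. The single libraries were spread over all 4 replicates, and no explanation was tested for these genes.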

How the results depend on the processing

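The alternatives that were chosen after seeing the data are length-matched random lists, length and GC terms, removal of X- and Y-linked genes, TPM over protein-coding genes and V genes without pseudogenes. The detected genes numbered 9296 to 11957, the lists detected above other genes 9 to 12 and those below 4 to 6, and the effective numbers of V genes moved by less than 1 SD under the alternatives run. The lowest replicate correlation was 0.989 with a pseudocount of 0.1, 0.997 without a filter and 0.989 with log2 CPM. The variable genes numbered 617 with a common dispersion (51 shared with the 94), 43 by DESeq2 dispersion outliers (38 shared) and 38 to 87 leaving out 1 replicate, where fewer libraries were fitted. The variable lists numbered 0 with log2 CPM, 3 with length-matched random lists and 1 to 7 leaving out 1 replicate. Among the 5 called lists the highest adjusted p was 0.0653 with a pseudocount of 0.1 and 0.130 with length-matched random lists (permutation tests). Of 9 alternatives, T-cell activation passed in 8 and amino-acid and ER stress in 6. T-cell activation failed with log2 CPM and TMM factors, where it had the highest adjusted p of the 5 lists (0.959, permutation test). Glycolysis, the interferon response and naive and central memory passed in 5 each. As library composition by TPM, which divides by length, mitochondrial genes took 1.77%, ribosomal protein genes 9.38%, histone cluster genes 0.0152%, immunoglobulin genes 0.0421%, T-cell receptor genes 1.19%, the 2 lincRNA models over the ribosomal RNA repeat 0.428%, protein-coding genes 94.6% and the 10 genes of highest TPM of any type, another set than the 10 with the most counts, 6.77%. By counts the share of Trbv13-2 was 12.1% and the share of Trav14n-3 was 5.91%. Results without a call changed sign: the contrast Ifng against Il4 was -0.0512 with a pseudocount of 0.1 and -0.17 to 0.18 leaving out 1 replicate, the contrast Xist against Ddx3y -0.89 to 3.57, list detection: CD8 and cytotoxic -7.00 percentage points at a TPM of 5 and list detection: interferon response -5.99 to 0.271 points leaving out 1 replicate. Of the levels of named genes, 31 moved by over 1 SD with TPM over protein-coding genes. Unless the construction shows it, the cause was not tested. The posterior-mean TPM could not be run, since the files hold counts. No paired analysis was possible because there is 1 group. Depth limits genes near the floor, such as Ifng with 8 to 64 counts.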

Other observations

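The gene families in this paragraph were picked by symbol after the values were seen. Several ligands of the TNF superfamily were abundant: Tnfsf11, which encodes the cytokine RANKL, stood at 1076 ± 40.4 TPM (SD, n = 4), Tnfsf8 at 549 ± 29.1, Cd70 at 245 ± 10.8 and Tnfsf4, the ligand of the product of Tnfrsf4, at 189 ± 7.78. Of 39 interleukin and colony-stimulating factor genes 11 were detected, and after Il2 the highest was Il3 at 270 ± 43.0, with Lif at 140 ± 8.79. The receptor genes Il2rg, Il2rb and Il21r stood at 558 ± 20.6, 533 ± 33.1 and 456 ± 24.1. Of 23 chemokine receptor genes 8 were detected, and Cxcr4 stood at 6.89 ± 1.59. The integrin genes Itgal and Itgb2, which encode the chains of LFA-1, stood at 591 ± 54.4 and 444 ± 16.7. All 8 genes of the SOCS family were detected, led by Cish at 143 ± 8.61. In the BCL2 family the anti-apoptotic genes Bcl2l1 and Mcl1 stood at 456 ± 16.1 and 315 ± 8.71, beside Bax. Ighd stood at 16.8 ± 3.51 TPM, and the class II regulator gene Ciita at 0.0894 ± 0.0603 beside the abundant Cd74.

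In the tests that follow, all but those of escape genes, GC content and thinning to the smallest total were chosen after the result was seen; other X-linked genes (Kdm6a, Eif2s3x, Pbdc1 and 5530601H04Rik) had been seen before the 4 tested were fixed.

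Xist and the 4 Y-linked genes of the fixed list (Ddx3y, Eif2s3y, Uty and Kdm5d) took opposite values in the same libraries. Gm47283 and Mid1-ps1, placed on the Y chromosome, had counts in replicates 1 and 2 as well and do not bear on this division. Xist was 1.06 lower on the log2 scale in replicate 2 than in replicate 1. Kdm5c, Ddx3x, Ftx and Jpx, known to escape X inactivation, varied more than random lists of 4 from 405 X-linked genes (one-sided permutation p = 0.0108), and their mean deviation was 0.51, 0.01, -0.14 and -0.37 in replicates 1 to 4. Cells of both sexes within 1 library are argued against, since the sum of those 4 Y-linked genes in the libraries with Xist was at most 0.261% of the lowest sum in the others, and a length trend gave 24.8% of the Xist difference. As CPM, the count scaled by the library total, Xist stood at 1705, 811, 4.41 and 2.07 in replicates 1 to 4. The sum of those 4 Y-linked genes stood at 0.359, 0.579, 235 and 222 CPM. These values argue against 1 animal as the source of all 4 libraries. Animals of different sex may account for the pattern. Some of the called X-linked genes divided as Xist did. In replicates 1 to 4, Kdm6a deviated by 0.45, 0.31, -0.29 and -0.47, and Eif2s3x by 0.40, 0.35, -0.37 and -0.39. Pbdc1 deviated by 0.43, 0.32, -0.39 and -0.37, and 5530601H04Rik by 0.40, 0.45, -0.46 and -0.39. Other called X-linked genes, Xlr3b and Gm38020, did not divide in this way. Jpx and Ftx in replicate 1 (1.09 and 0.52) contributed most to the escape-gene mean, and replicate 2 lay near 0. The escape-gene test alone therefore does not establish a division by sex. The labels give no sex and 1 donor identifier for all 4 libraries, why Xist differed between replicates 1 and 2 stayed open, and the design gives no group by which to test a biological explanation.

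Short genes shifted together between libraries: the median log2 deviation of autosomal genes of up to 1 kb was -0.04, 0.18, -0.23 and 0.09 in replicates 1 to 4, and that of genes over 8 kb was 0.04, -0.10, 0.09 and -0.03. For 77 ribosomal protein genes, a GC trend left 96.5% of the SD over libraries, which argues against GC content, while thinning to the smallest total left 99.9% but moved these abundant genes by a median of 0.00185 on the log2 scale, too little to decide on depth. Replicates 2 and 3 were closest in total (a ratio of 1.08) and yet differed by 0.50 on the log2 scale, 100% of the range over the libraries, which argues against a trend with the library total as the whole cause. A trend on summed exon length fitted on other genes left 59.8% of the SD, between the bounds set for and against length. Length may therefore account for part. The SD left, 0.125, exceeded that of random lists of the same summed exon lengths (permutation p = 0.0001, the smallest that 10000 lists can give). This argues against summed exon length as the whole cause for these genes. Transcript length itself was not measured, so the test does not decide on it. RNA integrity and fragment size were not measured here, and no biological explanation was tested.

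Histone mRNAs of the replication-dependent clusters lay near the floor although the cell-cycle genes were abundant. The median over 65 histone genes was 0.845 TPM, 0.00389 of the 217 TPM median of the cell-cycle list, and Hist1h4i was the highest at 29.9 ± 1.87 TPM. The 8 histone genes with at least 90% unique sequence had a median of 1.57 TPM, 0.00723 of the cell-cycle median. For these genes, this argues against reads left uncounted because histone copies share sequence. They were Hist1h1a, Hist1h1b, Hist1h1c, Hist1h1d, Hist1h1t (0 counts in all libraries), Hist2h2be, Hist2h4 and Hist4h4. For histone genes with less unique sequence, the effect of uncounted shared reads was not tested. Poly(A) selection is a candidate explanation, since these mRNAs lack a poly(A) tail, and it would go with the name of the linked library protocol and not with the total RNA label. The test cannot separate it from other causes of low histone mRNA, and no biological explanation was tested.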
